A study of Drosophila melanogaster with 9 samples.

How the data were processed

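RNA was measured by sequencing in embryos of 3 Drosophila genotypes, OreR, obe1/obe2 and obe2/Df, with 3 libraries each. Total RNA was extracted with Trizol from about 50 embryos per library and made into TruSeq v2 libraries, which were sequenced on a HiSeq2500, per the labels. The labels say that RNA was isolated in triplicate and do not say that replicates came from separate crosses, so p-values measure only the spread between these libraries, which may be technical. The submitters' processing notes name STAR, Cuffdiff, Cufflinks 2.1.1 and genome build dm3, without saying which step each served. The file headers and names point to featureCounts and DESeq. The gene annotation, the read filters and the DESeq version are not given in the sources used here. The signal values of the deposited matrix are gene read counts that the authors divided by 1 size factor per library. The deposited tables of the 2 comparisons with OreR give a fold, which the authors made as the ratio of group mean to OreR mean, and a p-value with an adjusted p-value, which the authors computed over genes.

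Each value in the matrix was a whole multiple of its library's smallest value. Dividing by it recovered whole reads for 100% of values within 0.001 of a read. Recovered reads ranged from 61007517 to 123121486 per library. The 10 most abundant genes took 4.54% to 5.34% of a library. A chi-square test of replicate pairs gave 50.3 to 283 per degree of freedom, so no pair agreed within sampling noise and each library was counted. The matrix held 15334 genes. Of these, 11817 matched the reference annotation (Release 6 plus ISO1 MT) by current symbol, 3052 by a synonym and 465 not at all. The reference was used for names, chromosome arms and gene order alone, since the authors' build was dm3, and no positions are given. The authors' deposited tables held 5 gene names turned into dates and 6 genes that the matrix does not list, which were not used here.

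Genes with a mean of at least 10 normalized counts over the 9 libraries were tested with limma 3.58.1 in R 4.3.3, on log2(normalized count + 1), with a mean-variance trend and all 3 groups in 1 fit. The 4 contrasts were obe1/obe2 against OreR, obe2/Df against OreR, obe2/Df against obe1/obe2, and the mean of both obe groups against OreR. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 8346 tested genes are called higher or lower. The 30 gene lists held 516 symbols, of which 13 were not found. They cover epithelial polarity and junctions, gastrulation movement, cellularization, patterning, homeotic, maternal, early zygotic, sex determination, germline, piRNA, RNA decay, spliceosome, spliceosomal helicase, ribosomal, heat shock, innate immunity, detoxification, apoptosis, histone, later embryonic tissue, hemocyte, and adult carry-over genes. Lists with at least 5 tested members were tested with camera (preset correlation 0.01, then an estimated one) and fry. Some genes are in more than 1 list, so list calls are not independent. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names obe and crb, the 10 largest rises and falls in each obe group among called genes with a mean of at least 50 and no overlap between groups, up to 4 members of each list with a called gene, the 10 largest shared rises and falls, and the 5 largest rises and falls between the obe groups. Names outside the rule are given as chosen after their values were seen. Where a gene named in 1 comparison is also given in another, that value is such an addition.

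On simulated data, OreR-like libraries with added changes were analysed in the same way. With changes of 1.5, 2 and 4-fold in 67, 67 and 66 genes, 43.3%, 68.7% and 90.9% were called in the obe1/obe2 comparison, with 10 false calls, and 29.9%, 47.8% and 77.3% in the obe2/Df comparison, with 7. In each comparison 1 list of 15 genes lowered 2-fold was called, and 0 unchanged lists were. Genes were simulated independently, so this does not test the preset correlation on lists whose members vary together. All groups had the same spread per gene, and each comparison drew its own genes to change. The shares of the 2 comparisons therefore do not rank them by sensitivity. Far fewer genes were changed than were called in the data, so the shares need not hold there. Alternatives were pseudocounts of 0.5 and 5, no filter, a minimum mean of 50, TMM factors, quantile normalization, array weights, the replicate number as a block, a fold minimum of 2, the authors' deposited tables, leaving out each library, and count models on the recovered reads, edgeR 4.0.16 and DESeq2 1.42.0. The count models called 1811 (edgeR) and 2440 (DESeq2) genes in obe1/obe2 and 4984 and 5297 in obe2/Df. Fits on the 6 libraries of each pair of groups, and gene families read from symbols, were added after seeing the data. Figures were drawn with Python 3.11.15. Gene totals do not measure the splicing of crb, and no read-level or isoform data were analysed here.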

Results

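RNA sequencing was run on embryos of the fruit fly Drosophila melanogaster of 3 genotypes, with 3 libraries per genotype. OreR is the wild-type strain Oregon-R. The genotypes obe1/obe2 and obe2/Df carry mutations in obe (CG5205, obelus), a gene on chromosome 3 that encodes a Ski2-family RNA helicase. Both carry the obe2 allele, and the other chromosome carries obe1 or Df, which in fly nomenclature stands for a deficiency. The labels name neither the lesions nor the deficiency. Each library came from about 50 embryos aged 3 h, at late stage 5 to early stage 6, when the blastoderm has formed cells and gastrulation begins. Whole reads recovered from the deposited matrix totalled 71917538, 101171295 and 69120633 in OreR replicates 1 to 3, 84162382, 87237599 and 65245053 in obe1/obe2 and 123121486, 61007517 and 89515347 in obe2/Df. Of 15334 genes, 8346 had a mean of at least 10 normalized counts over the 9 libraries and were tested. Levels are given as mean ± SD in normalized counts (n = 3 libraries per group), and changes as log2 fold change ± SE from the fit.

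On the first principal component, which held 56.9% of the variance, the OreR libraries lay at -61.5, -55.9 and -51.2, and the obe1/obe2 libraries at 10.5, -32.4 and -15.2. The obe2/Df libraries lay at 108.5, 47.5 and 49.8. Replicate 1 of obe2/Df therefore lay apart from the other 2 of its group. The second component held 20.2% and separated obe1/obe2 (-36.2, -51.8 and -46.5) from the other groups (5.12 to 31.6).

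The first question was how the RNA of obe itself and of crb differed between genotypes. The gene crb encodes Crumbs, an apical polarity protein, and the series concerns the splicing of its RNA. Gene totals do not measure splicing. The RNA of obe was 7056 ± 1381 normalized counts in OreR (5850, 8562 and 6755 per library). It fell to 731 ± 79.7 in obe1/obe2 (821.3, 672 and 698.3), a log2 fold change of -3.26 ± 0.20 (adjusted p = 1.92e-05). In obe2/Df it fell to 235 ± 47.8 (276.7, 245.3 and 182.9), a log2 fold change of -4.91 ± 0.20 (adjusted p = 1.61e-06). The obe groups differed from each other by -1.65 ± 0.20 (adjusted p = 0.00164). The authors' deposited table gives a fold of 0.104 for obe1/obe2 (adjusted p = 4.22e-09) and 0.0333 for obe2/Df (adjusted p = 6.2e-17). The crb total was 13352 ± 1838 in OreR, 10799.6 ± 1405 in obe1/obe2 and 15905 ± 846 in obe2/Df. It did not pass the test in obe1/obe2 (-0.31 ± 0.12, adjusted p = 0.1) or in obe2/Df (0.26 ± 0.12, adjusted p = 0.0884). It was higher in obe2/Df than in obe1/obe2 (0.57 ± 0.12, adjusted p = 0.0064), with the 3 obe2/Df libraries between 15304 and 16872 and the 3 obe1/obe2 libraries between 9529 and 12309. Without obe1/obe2 replicate 1 the obe1/obe2 change passed (-0.40, adjusted p = 0.0351), and without OreR replicate 2 the obe2/Df change passed (0.36, adjusted p = 0.0303). With array weights both passed (-0.28, adjusted p = 0.0322, and 0.29, adjusted p = 0.0252), as did obe2/Df after quantile normalization (0.34, adjusted p = 0.0152). The authors' deposited table lists crb at a fold of 0.809 in obe1/obe2 (adjusted p = 1) and 1.19 in obe2/Df (adjusted p = 0.918).

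**Figure D1:**
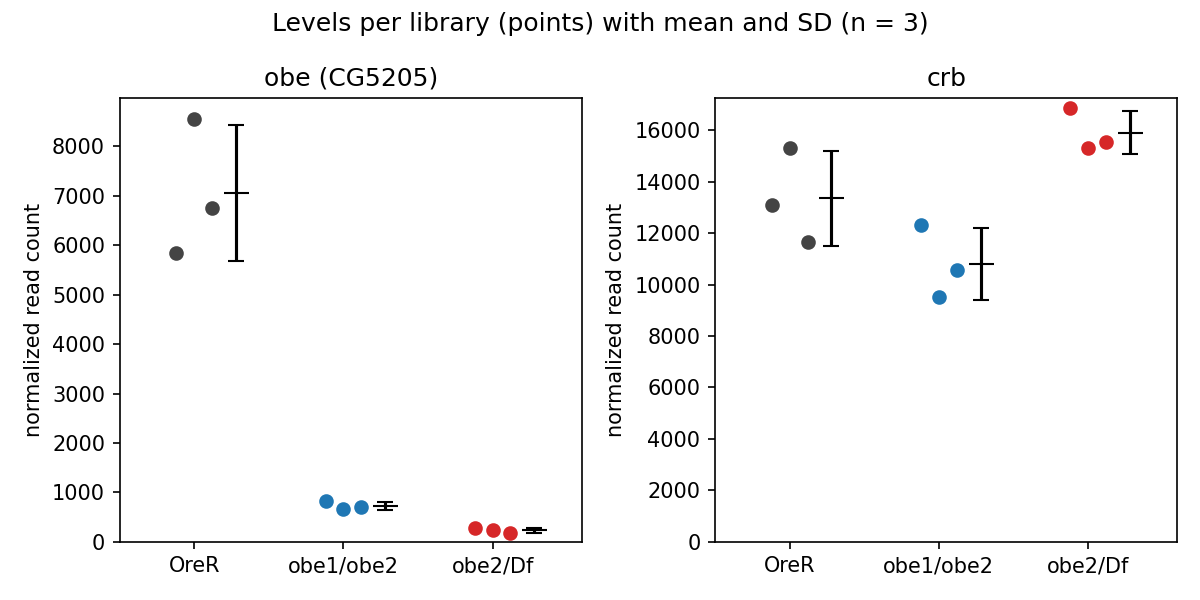
Normalized counts of obe and of crb in each of the 9 libraries (y axis from 0), with 1 point per library and lines for the group mean ± SD. The obe values lie between 5850 and 8562 in OreR, between 672 and 821.3 in obe1/obe2 and between 182.9 and 276.7 in obe2/Df.

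The comparison of obe1/obe2 with OreR asked which other RNAs differ when both chromosomes carry an obe allele. Several genes rose or fell steeply. CG11034 rose from 42.0 ± 6.42 to 4444 ± 165 (6.70 ± 0.14, adjusted p = 4.94e-08), CG14879 from 11.1 ± 3.83 to 1568 ± 44.7 (7.06 ± 0.22, adjusted p = 6.19e-07) and CG7433 from 350.4 ± 170.0 to 30147 ± 2283 (6.54 ± 0.30, adjusted p = 6.1e-06). The retrotransposon-Gag relatives Arc1 and Arc2 fell, Arc1 from 17469 ± 1136 to 524 ± 272 (-5.18 ± 0.30, adjusted p = 1.52e-05) and Arc2 from 2083 ± 179 to 47.6 ± 10.9 (-5.44 ± 0.27, adjusted p = 7.92e-06). CG13937 fell from 7755 ± 271 to 67.1 ± 47.2 (-7.08 ± 0.63, adjusted p = 0.000118) and the cytochrome P450 gene Cyp6d2 from 506 ± 245 to 6.71 ± 5.41 (-6.13 ± 0.68, adjusted p = 0.000365). The other largest rises were those of CG12560 (7.70 ± 0.47, 7.08 without OreR replicate 1), CG13032 (7.51 ± 1.06) and the ionotropic receptor Ir76a (7.08 ± 0.71, 7.81 without OreR replicate 1, 6.12 without OreR replicate 3). The other largest falls were those of CG10962 (-5.39 ± 0.28), CG31955 (-5.28 ± 0.39), CG12592 (-5.13 ± 0.25) and CG6106 (-4.95 ± 1.03, -5.75 without obe1/obe2 replicate 1, -3.59 without obe1/obe2 replicate 3). Sdic3 (-5.21 ± 0.48, -4.59 without obe1/obe2 replicate 1) also fell, but it is 1 of several near-identical copies, so its reads are of uncertain origin. For genes at or near 0 in 2 or more libraries of a group the levels are given alone. Dscam4 was at 2.82 ± 4.88 in OreR and 1874 ± 154 in obe1/obe2 (adjusted p = 0.000888), and the serine protease gene Jon65Ai at 268 ± 125 and 1.83 ± 3.17 (adjusted p = 0.000353). The genes mey and fd96Ca were at 0 in OreR and at 128 ± 52.6 and 99.5 ± 30.4 in obe1/obe2 (adjusted p = 1.05e-05 and 3.98e-05). Oseg5 was at 0.564 ± 0.977 and 235 ± 121 (adjusted p = 0.000111).

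In all, 1889 of 8346 genes (22.6%) passed an adjusted p of 0.05, 916 higher and 973 lower, and 3095 had an unadjusted p under 0.05. Of the 1889, 694 differed at least 2-fold (427 higher, 267 lower) and 169 at least 8-fold (116 higher, 53 lower). After quantile normalization 1129 were higher and 776 lower, 59.3% against 48.5% as deposited. With TMM factors 49.3% and with edgeR 50% were higher, so the balance moved with quantile normalization and little with TMM factors or edgeR. The count was 2211 without obe1/obe2 replicate 1, 1301 without OreR replicate 1 and 3451 with array weights. The lower genes numbered 629 without OreR replicate 1 and 619 without OreR replicate 3, and those lower at least 2-fold 423 without obe1/obe2 replicate 1.

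The gene lists of stress, detoxification and the ribosome had called genes in obe1/obe2. Of 8 heat shock genes 4 were lower and 0 higher (5 lower adjusted over the list alone), with a median of -0.55. Hsp26, a small heat shock protein gene, fell from 23838 ± 4096 to 7379 ± 4929 (-1.87 ± 0.37, adjusted p = 0.00747), and Hsc70-4, a constitutive Hsp70 chaperone, from 433479 ± 11197 to 306917 ± 27494 (-0.50 ± 0.09, adjusted p = 0.00456). Without OreR replicate 3, 2 of the 8 passed. Of 18 detoxification genes 6 were higher and 5 lower (8 and 5 adjusted over the list alone). The glutathione S-transferases split, with GstD1 up from 71.3 ± 29.8 to 2312 ± 1697 (4.85 ± 0.49, adjusted p = 0.000233) and GstE1 (-2.54 ± 0.23), GstE6 (-3.80 ± 0.38) and GstE7 (-3.46 ± 0.25) down. The list's median was 0.95 and its mean 0.69, with camera pointing up and fry down, so no single direction describes the list. Of 28 ribosomal protein genes 7 were lower and 0 higher (7 and 0 adjusted over the list alone, median -0.11), among them sta (-1.72 ± 0.25, adjusted p = 0.00147), RpLP0 (-1.25 ± 0.23), RpL3 (-0.62 ± 0.09) and RpS27A (-0.55 ± 0.09). The ribosomal list did not pass the camera test (adjusted p = 0.19), but passed it without OreR replicate 2 (adjusted p = 0.0264) and without obe1/obe2 replicate 2 (adjusted p = 0.0176). With all libraries and an estimated correlation its adjusted p was 0.978.

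Further lists in obe1/obe2 cover epithelial polarity, tissue movement and RNA processing. In the apical polarity list, with 0 higher and 1 lower of 10 (0 and 1 adjusted over the list alone), sdt, which encodes the Crumbs partner Stardust, fell from 3863 ± 986 to 1913 ± 173 (-0.98 ± 0.20, adjusted p = 0.00867). The basolateral genes l(2)gl (0.52 ± 0.09, adjusted p = 0.00501) and dlg1 (0.65 ± 0.13, adjusted p = 0.00818) rose, in a list with 2 higher and 1 lower of 10 (3 and 3 adjusted over the list alone), with 4 higher without OreR replicate 2. In the actomyosin list, with 1 higher and 3 lower of 16 (1 and 3 adjusted over the list alone), the GTPase gene Rho1 fell from 37192 ± 2884 to 23521 ± 2088 (-0.66 ± 0.08, adjusted p = 0.000772) and the Toll-family receptor gene Tollo from 5110.2 ± 616 to 1246 ± 678 (-2.16 ± 0.34, adjusted p = 0.00232). The adherens junction list had 1 higher and 1 lower of 13 (1 and 0 adjusted over the list alone), with 4 higher without OreR replicate 2. The actomyosin list passed fry on direction, downward (adjusted p = 0.0151). The spliceosome list had 3 higher and 3 lower of 29 (3 and 5 adjusted over the list alone), with Hrb98DE up (0.49 ± 0.10, adjusted p = 0.00866). The RNA decay list had 2 higher and 3 lower of 22 (2 and 4 adjusted over the list alone), with the exosome helicase gene l(2)35Df up (0.53 ± 0.09, adjusted p = 0.00376) and the nonsense-mediated decay gene Upf3 down (-0.58 ± 0.11, adjusted p = 0.00614). The list includes obe itself (-3.26), which counts among its lower members and pulls its mean down. Its median was 0.07 and its mean -0.14, with camera pointing up and fry down. It had 4 higher without OreR replicate 2 and 5 lower without obe1/obe2 replicate 1. The helicase list had 0 higher and 2 lower of 11 (0 and 2 adjusted over the list alone), with pea down (-0.32 ± 0.06, adjusted p = 0.00687), and passed fry on direction, downward (adjusted p = 0.0151). In the piRNA list, with 2 higher and 2 lower of 18 (2 and 2 adjusted over the list alone), rhi, which marks piRNA clusters, rose from 4475 ± 369.6 to 8842 ± 846 (0.98 ± 0.09, adjusted p = 0.00014) and the small-RNA methyltransferase gene Hen1 fell from 4934 ± 363 to 2935 ± 84.7 (-0.75 ± 0.08, adjusted p = 0.000376).

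Each zygotic patterning list had 0 or 1 called gene in obe1/obe2. Early zygotic activation had 1 higher and 0 lower of 20 (0 and 0 adjusted over the list alone) and a median of -0.28. The gap and terminal list had 0 higher and 0 lower of 14 (0 and 0 adjusted over the list alone). The pair-rule list had 1 higher and 0 lower of 16 (1 and 0 adjusted over the list alone) and the dorsal-ventral list 0 higher and 1 lower of 26 (0 and 0 adjusted over the list alone). Cellularization had 0 higher and 0 lower of 10 (0 and 0 adjusted over the list alone) and the homeotic list 0 higher and 0 lower of 11 (0 and 0 adjusted over the list alone). The early zygotic means per library, relative to OreR, were -0.89 in obe1/obe2 replicate 1, 0.22 in replicate 2 and -0.51 in replicate 3, so replicate 1 lay lowest. Of the maternal lists, coordinate determinants had 0 higher and 2 lower of 15 (0 and 2 adjusted over the list alone) and cleared maternal RNAs 1 higher and 3 lower of 18 (1 and 4 adjusted over the list alone). Pole cell genes had 2 higher and 1 lower of 14 (2 and 1 adjusted over the list alone). When obe1/obe2 replicate 1 was left out, 5, 5 and 7 genes of these 3 lists were lower and 0 higher. The histone list had 0 higher and 3 lower of 5 (0 and 4 adjusted over the list alone), all 3 of them lost without 1 or more libraries. The apoptosis list had 1 higher and 0 lower of 17 (1 and 0 adjusted over the list alone), the pro-death gene W (hid; 0.57 ± 0.13, adjusted p = 0.0141). The sex determination list had 1 higher and 1 lower of 19 (0 and 1 adjusted over the list alone), the lower 1 being her (-0.74 ± 0.10, adjusted p = 0.00138). Among lists of other tissues, neuron had 1 higher and 0 lower of 7 (1 and 0 adjusted over the list alone), with the complexin gene cpx up from 3.84 ± 2.54 to 84.8 ± 10.3 (4.26 ± 0.40, adjusted p = 0.000157). Muscle had 1 higher and 0 lower of 7 (1 and 0 adjusted over the list alone) and hemocytes 0 higher and 0 lower of 10 (0 and 0 adjusted over the list alone). Trachea, cuticle and gut had 0 higher and 2 lower of 6 (0 and 3 adjusted over the list alone), with the chitinase gene Cht2 down (-1.80 ± 0.38, adjusted p = 0.00942). The yolk and fat body list had 2 higher and 1 lower of 5 (2 and 2 adjusted over the list alone). In it Lsp1gamma rose from 20.6 ± 13.2 to 432 ± 90.1 (4.49 ± 0.44, adjusted p = 0.000192) as did Rfabg (1.10 ± 0.19), while Cp1, a cysteine proteinase gene, fell (-0.63 ± 0.08, adjusted p = 0.000711). The innate immunity list had 1 higher and 0 lower of 3 (1 and 0 adjusted over the list alone). In it Tep2 rose from 18.6 ± 6.23 to 485 ± 84.6 (4.67 ± 0.29, adjusted p = 2.17e-05), and PGRP-SB1 (0.21 ± 0.35, adjusted p = 0.692) and PGRP-SC2 (-0.02 ± 0.90, adjusted p = 0.99) did not pass. Of the 28 lists with at least 5 tested members, camera called 0 at its preset correlation and 0 with an estimated correlation, with 4 at an unadjusted p under 0.05 (heat shock, ribosomal, histone and trachea lists). In the piRNA and sex determination lists the medians (-0.02 and -0.08) were negative while camera pointed up. The fry test called 6 on direction and 18 on change in either direction. In fry, the first p tests whether members move on balance one way and the second whether they change either way, and neither compares a list with other genes.

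The comparison of obe2/Df with OreR asked the same for 1 obe allele over the deficiency. In 5 lists of genes that the embryo switches on in its first hours of transcription, most members were lower in obe2/Df. Of 20 early zygotic activation genes 16 were lower and 0 higher (18 and 0 adjusted over the list alone), with a median log2 fold change of -4.82. Of 14 gap and terminal genes 10 were lower and 0 higher (10 and 0 adjusted over the list alone, median -3.95), of 16 pair-rule and segment polarity genes 11 and 0 (11 and 0 adjusted over the list alone, median -3.55), of 10 cellularization genes 8 and 0 (8 and 0 adjusted over the list alone, median -3.23), and of 26 dorsal-ventral genes 16 lower and 3 higher (16 and 3 adjusted over the list alone, median -2.86). The camera test called these 5 lists at its preset correlation (adjusted p = 0.00194, 0.0193, 0.00996, 0.00813 and 0.0418). It called none of the 5 with an estimated correlation (adjusted p = 0.857 for each). The lists overlap: run is in the early zygotic and pair-rule lists, tll in early zygotic and gap, and slp1 in gap and pair-rule. The fry test passed the early zygotic, gap, pair-rule and cellularization lists on direction (adjusted p = 0.0241, 0.044, 0.0399 and 0.00735) and not the dorsal-ventral list (adjusted p = 0.093). Replicate 1 of obe2/Df lay farthest down, with an early zygotic mean of -6.54 against -2.34 and -3.37 in replicates 2 and 3, and a gap list mean of -6.56 against -2.01 and -2.14. Without it the medians were -3.29 (early zygotic, 16 lower), -2.67 (gap, 9 lower), -2.22 (pair-rule, 10 lower), -2.57 (cellularization, 8 lower) and -2.10 (dorsal-ventral, 12 lower), and camera called the 5 lists. Without obe2/Df replicate 2 the medians were -5.74 (early zygotic), -4.77 (gap) and -4.37 (pair-rule), and without replicate 3 the dorsal-ventral median was -3.50. Leaving out OreR replicate 1 gave 6 lower gap genes, and leaving out OreR replicate 2 gave 10 lower dorsal-ventral and 7 lower pair-rule genes. The dorsal-ventral call was lost without OreR replicate 1 (adjusted p = 0.0525), OreR replicate 2 (0.142) or obe1/obe2 replicate 2 (0.0582), and in a fit on the 6 libraries compared (0.0563).

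The size of the fall varied between these genes. The cellularization genes slam, needed for the growing cell membrane, and kuk, a nuclear lamina protein gene, fell from 103502 ± 20666 to 22909 ± 2856 (-2.17 ± 0.27, adjusted p = 0.000415) and from 154153 ± 27484 to 66170.1 ± 4641 (-1.21 ± 0.17, adjusted p = 0.000683). CG14561 of the early zygotic list fell from 6594 ± 1165 to 2719 ± 185 (-1.27 ± 0.19, adjusted p = 0.00082). The neural precursor gene dpn, here in the sex determination list, fell from 4102 ± 386 to 406 ± 224 (-3.51 ± 0.43, adjusted p = 0.000376), the segment polarity ligand hh from 62.1 ± 19.0 to 4.40 ± 2.81 (-3.67 ± 0.60, adjusted p = 0.0013) and the epidermal growth factor pathway protease rho from 1114 ± 499 to 198 ± 57.1 (-2.44 ± 0.43, adjusted p = 0.00184). Other falls moved in size when single libraries were left out. The gap gene Kr fell from 6129.7 ± 1911 to 527 ± 361 (-3.91 ± 0.71, adjusted p = 0.00217, -3.02 without obe2/Df replicate 1), tll from 3870.3 ± 1004 to 234 ± 199 (-5.29 ± 1.29, adjusted p = 0.00752, -3.45 without obe2/Df replicate 1, -6.28 without obe2/Df replicate 2, -6.15 without obe2/Df replicate 3) and gt from 5056 ± 1127 to 286 ± 238 (-5.09 ± 1.08, adjusted p = 0.00415, -3.57 without obe2/Df replicate 1, -5.93 without obe2/Df replicate 2, -5.76 without obe2/Df replicate 3). The cellularization gene nullo fell from 7807 ± 1038 to 324 ± 431 (-5.79 ± 1.004, adjusted p = 0.00176, -4.56 without obe2/Df replicate 1, -7.06 without obe2/Df replicate 2), and the pair-rule gene ftz from 2543 ± 615 to 197 ± 162 (-4.57 ± 1.04, adjusted p = 0.00573, -3.11 without obe2/Df replicate 1, -5.37 without obe2/Df replicate 2, -5.22 without obe2/Df replicate 3).

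Maternal and germline lists had called genes in both directions in obe2/Df. Of 14 pole cell and germ plasm genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone, median 0.63). These included pgc, which represses transcription in pole cells (0.69 ± 0.17, adjusted p = 0.00715), wun2, a lipid phosphatase gene of germ cell survival (0.85 ± 0.12, adjusted p = 0.000841), and ovo (1.03 ± 0.24, adjusted p = 0.00579), while nos fell (-0.97 ± 0.14, adjusted p = 0.000801). The list did not pass camera (adjusted p = 0.16), and 6 were higher without obe2/Df replicate 1, with a median of 0.59. The cleared maternal RNAs had 7 higher and 4 lower of 18 (7 and 4 adjusted over the list alone) and a median of 0.17, with the mitotic phosphatase gene stg higher (0.94 ± 0.15, adjusted p = 0.00139). Their medians per library, relative to OreR, were 0.27, 0.17 and 0.15. The coordinate determinants had 6 higher and 5 lower of 15 (6 and 6 adjusted over the list alone), with dl up from 4531 ± 393 to 11428 ± 1211 (1.33 ± 0.28, adjusted p = 0.00418) and ea down from 7404 ± 351 to 1959.7 ± 221 (-1.92 ± 0.11, adjusted p = 1.09e-05). The list's median was 0.03 and its mean 0.14, while camera pointed down. The gene ea is 1 of the 20 nearest tested genes on 1 side of obe, of which 15 were lower in obe2/Df than in obe1/obe2. The piRNA list had 8 higher and 4 lower of 18 (8 and 4 adjusted over the list alone), with rhi up (0.78 ± 0.09, adjusted p = 0.000292) and AGO3 down (-1.08 ± 0.10, adjusted p = 9.34e-05).

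The splicing and ribosomal lists had more lower than higher called genes in obe2/Df. Of 29 spliceosome genes 20 were lower and 0 higher (1 higher and 20 lower adjusted over the list alone), with a median of -0.38 (camera adjusted p = 0.00285, and adjusted p = 0.857 with an estimated correlation). U2af38, a splice-site recognition factor, fell from 17274 ± 1411 to 11119 ± 943 (-0.64 ± 0.10, adjusted p = 0.001), crn (-0.57 ± 0.08) and SmB (-0.67 ± 0.10) also fell, and 17 were lower without obe2/Df replicate 1. The spliceosomal helicase list had 2 higher and 7 lower of 11 (2 and 7 adjusted over the list alone), with pea (-0.87 ± 0.06) and Hel25E (-0.56 ± 0.09) lower. Its higher members included mus301, a DNA repair helicase gene (1.20 ± 0.20, adjusted p = 0.00151). Of 28 ribosomal protein genes 11 were lower and 0 higher (8 lower adjusted over the list alone, median -0.22, camera adjusted p = 0.00285, and adjusted p = 0.857 with an estimated correlation). RpL3 fell from 164574 ± 8030.2 to 81718 ± 5410.2 (-1.01 ± 0.09, adjusted p = 9.19e-05), and RpL10 (-0.57 ± 0.10) and RpS27A (-0.69 ± 0.09) also fell. The sex chromosome counting list had 3 higher and 13 lower of 19 (3 and 14 adjusted over the list alone), with a median of -0.59 (camera adjusted p = 0.0342, and adjusted p = 0.857 with an estimated correlation). It shares sisA, sc and run with the early zygotic list, so its call is not independent of that list's. Its falls included dpn (-3.51 ± 0.43) and the counting element sisA (-4.04 ± 1.17, -2.34 without obe2/Df replicate 1, -5.02 without obe2/Df replicate 2, -4.77 without obe2/Df replicate 3), and its rises msl-3 (0.46 ± 0.09). Its call was lost without OreR replicate 2 (adjusted p = 0.0559).

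Apart from the homeotic and neuron lists, the other lists with tested genes had called genes in both directions. The apoptosis and DNA damage list had 6 higher and 5 lower of 17 (6 and 5 adjusted over the list alone), with the DNA damage genes Ku80 from 563 ± 179 to 2760.3 ± 213 (2.33 ± 0.33, adjusted p = 0.000729), tefu (1.28 ± 0.15) and lok (0.99 ± 0.15) higher and Nc (-0.69 ± 0.09) lower. The adherens junction list had 2 higher and 6 lower of 13 (2 and 6 adjusted over the list alone), 4 higher without OreR replicate 2, with alpha-Cat (-0.72 ± 0.08, adjusted p = 0.00025) and arm (-0.68 ± 0.12) lower. The apical list had 1 higher and 4 lower of 10 (1 and 4 adjusted over the list alone), 4 higher without OreR replicate 2, with sdt (-0.85 ± 0.20) and aPKC (-0.29 ± 0.06) lower. It had a median of 0.21, a mean of 0.02 and a camera direction of down. The basolateral list had 2 higher and 4 lower of 10 (2 and 4 adjusted over the list alone), with cora (-2.83 ± 0.25) lower. The actomyosin list had 4 higher and 6 lower of 16 (4 and 6 adjusted over the list alone), 2 higher without OreR replicate 1, with RhoGEF2 higher (1.59 ± 0.26, adjusted p = 0.00126) and Rho1 (-0.79 ± 0.08) lower. The detoxification list had 5 higher and 6 lower of 18 (5 and 6 adjusted over the list alone), with Cyp6g1 (3.37 ± 0.41) higher and Cyp12d1-p (-3.91 ± 0.33) and GstE7 (-2.31 ± 0.25) lower. Its median was 0.17 and its camera direction down. It had 3 higher without OreR replicate 1 or 3 and 2 without obe2/Df replicate 1. The RNA decay list had 6 higher and 7 lower of 22 (6 and 7 adjusted over the list alone), with Rrp4 (1.37 ± 0.23) higher and Upf3 (-0.63 ± 0.11) lower. The list includes obe itself (-4.91), which counts among its lower members and pulls its mean down. Its median was 0.01 and its mean -0.13, and camera pointed down. The apoptosis median was 0.03 and its mean -0.22, and camera pointed up. The heat shock list had 2 higher and 3 lower of 8 (2 and 3 adjusted over the list alone), with Hsc70-4 (-0.69 ± 0.09) lower. The histone list had 1 higher and 4 lower of 5 (1 and 4 adjusted over the list alone), with His4r (-0.89 ± 0.12) lower. The homeotic list had 0 higher and 4 lower of 11 (0 and 1 adjusted over the list alone) and a median of -2.11, with exd (-0.51 ± 0.09) lower. It had 1 or 2 lower when OreR replicate 1 or 2, obe1/obe2 replicate 3 or obe2/Df replicate 1 or 2 was left out. Without obe2/Df replicate 3 it passed camera (adjusted p = 0.0145). With all libraries it did not pass at the preset (adjusted p = 0.141) or with an estimated correlation (adjusted p = 0.857). Of the marker lists, muscle had 1 higher and 2 lower of 7 (1 and 1 adjusted over the list alone) and hemocytes 1 higher and 1 lower of 10 (0 and 0 adjusted over the list alone). Neuron had 2 higher and 0 lower of 7 (2 and 0 adjusted over the list alone), with cpx (3.42 ± 0.40) higher. Trachea, cuticle and gut had 1 higher and 1 lower of 6 (1 and 1 adjusted over the list alone). The yolk and fat body list had 1 higher and 2 lower of 5 (1 and 2 adjusted over the list alone), with Lsp1gamma (2.69 ± 0.44) higher. In it Lsp1beta was at 25.6 ± 9.001 in OreR and 0.434 ± 0.752 in obe2/Df (adjusted p = 0.000704). In innate immunity, with 1 higher and 1 lower of 3 (2 and 1 adjusted over the list alone), Tep2 (6.71 ± 0.29) was higher, and PGRP-SC2 was lower, at 20.9 ± 14.6 in OreR and 1.09 ± 1.88 in obe2/Df (adjusted p = 0.009). The follicle cell list of chorion and vitelline membrane genes had 18 genes in the matrix and 0 above the filter, the highest mean being 6.96 normalized counts.

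The largest rises in obe2/Df included CG11034 from 42.0 ± 6.42 to 7624 ± 737 (7.48 ± 0.14, adjusted p = 1.89e-08), CG14879 from 11.1 ± 3.83 to 2184 ± 123 (7.54 ± 0.22, adjusted p = 5.24e-07) and the hyperpolarization-gated channel gene Ih from 17.3 ± 8.97 to 3869.8 ± 808 (7.82 ± 0.42, adjusted p = 7.98e-06). CG12560 (7.81 ± 0.47, 7.19 without OreR replicate 1), Ir76a (7.62 ± 0.71, 8.34 without OreR replicate 1, 6.65 without OreR replicate 3), CG10654 (7.59 ± 0.49, 6.97 without OreR replicate 1) and Sdic1 (7.37 ± 0.75, 6.37 without OreR replicate 1, 7.99 without OreR replicate 2; near-identical copies, reads of uncertain origin) were also among them. The gene mey was at 0 in OreR and at 188 ± 25.1 in obe2/Df (adjusted p = 4.37e-06), CG13532 at 3.78 ± 5.55 and 1390.5 ± 178 (adjusted p = 0.000136) and CG9766 at 0.564 ± 0.977 and 622 ± 131 (adjusted p = 1.09e-05). The largest falls were those of CG13937 (-9.48 ± 0.63, -8.82 without obe2/Df replicate 3), and of the transcription regulator genes Bro (-6.24 ± 0.97, -4.97 without obe2/Df replicate 1, -7.36 without obe2/Df replicate 2) and amos (-6.15 ± 1.16, -4.82 without obe2/Df replicate 1, -7.73 without obe2/Df replicate 2). The transcription factor gene ato was at 440.2 ± 122 in OreR and 24.5 ± 41.04 in obe2/Df (adjusted p = 0.00385). The signalling ligand scw (-5.92 ± 0.99, -4.70 without obe2/Df replicate 1, -7.16 without obe2/Df replicate 2) and CG15634 (-6.19 ± 1.06, -4.72 without obe2/Df replicate 1, -7.23 without obe2/Df replicate 2), CG18269 (-6.12 ± 1.02, -4.97 without obe2/Df replicate 1, -7.51 without obe2/Df replicate 2) and CG11929 (-6.03 ± 0.97, -4.70 without obe2/Df replicate 1, -6.87 without obe2/Df replicate 2) also fell steeply. The arginine methyltransferase gene Art2 fell from 429 ± 169 to 5.97 ± 3.63 (-5.996 ± 0.55, adjusted p = 0.000105). Jon65Ai was at 268 ± 125 in OreR and at 0 in obe2/Df (adjusted p = 0.000137). In all, 5050 genes (60.5%) passed the test, 2590 higher and 2460 lower, and 5441 had an unadjusted p under 0.05. Of the 5050, 1895 differed at least 2-fold (1266 higher, 629 lower) and 449 at least 8-fold (178 higher, 271 lower). After quantile normalization 2434 were higher and 2595 lower, which turned the larger side. TMM factors and edgeR left it, with 51.2% and 51.5% higher against 51.3% as deposited. Without obe2/Df replicate 1 the count was 4194, and 168 were lower at least 8-fold. Of the 28 lists, camera called 8 (9 at an unadjusted p under 0.05) and 0 with an estimated correlation, and fry called 15 on direction and 27 on change in either direction.

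**Figure D2:**
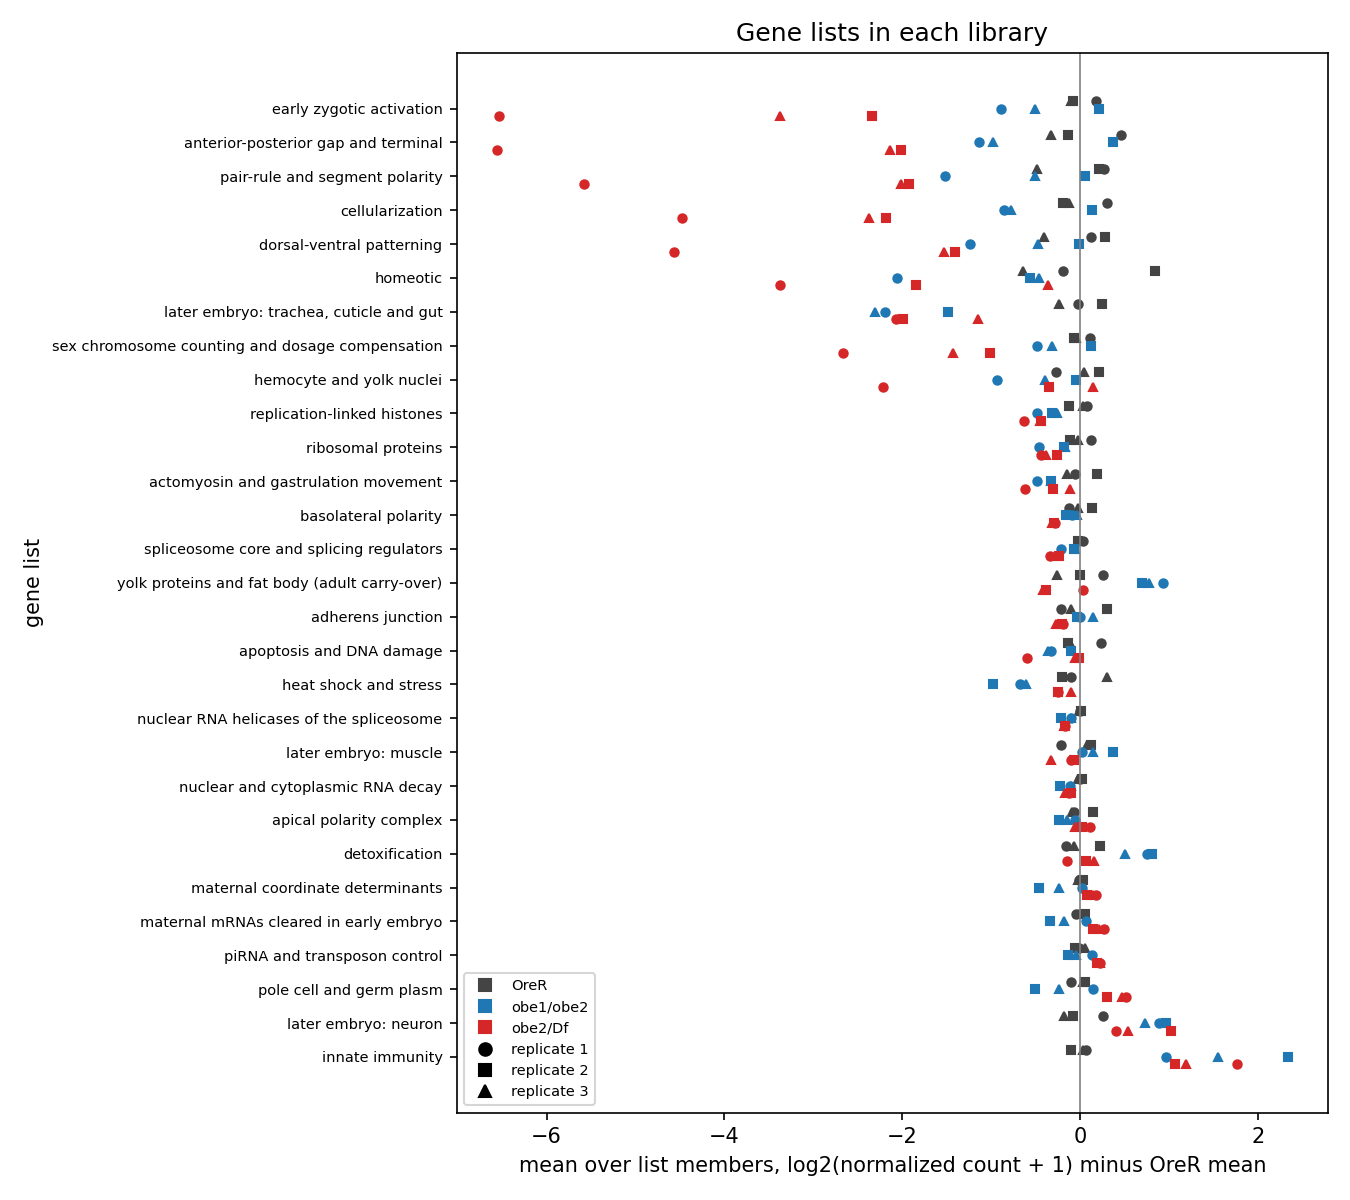
Mean over the members of each gene list in each library, as log2(normalized count + 1) minus the OreR mean (x axis), with 1 marker per library, coloured by group and shaped by replicate number. The early zygotic list lies at -6.54, -2.34 and -3.37 in obe2/Df and at -0.89, 0.22 and -0.51 in obe1/obe2.

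The next question was which changes both obe groups share. CG11034 and CG7433 rose in both, CG7433 to 30147 ± 2283 in obe1/obe2 and 30985 ± 912 in obe2/Df from 350.4 ± 170.0 in OreR (6.54 ± 0.30 and 6.59 ± 0.30). CG32364 rose from 29.2 ± 6.13 to 2219 ± 313 and 1961 ± 175 (6.21 ± 0.20 and 6.04 ± 0.20). Among the shared falls, CG13937 dropped from 7755 ± 271 to 67.1 ± 47.2 and 11.9 ± 7.39, and CG12592 from 1058 ± 93.0 to 29.9 ± 7.98 and 44.9 ± 5.82. The cell adhesion gene Con fell from 774 ± 86.6 to 56.8 ± 13.1 and 36.2 ± 8.16 (-3.77 ± 0.27 and -4.40 ± 0.27), and the calcium channel subunit gene Ca-beta from 151 ± 39.5 to 7.90 ± 2.98 and 5.35 ± 2.24 (-4.12 ± 0.43 and -4.61 ± 0.43). The other shared falls by the naming rule were those of CG30046 (-4.28 ± 0.34 and -5.33 ± 0.34), sano (-3.80 ± 0.35 and -3.67 ± 0.35), CG31955, Jon65Ai, CG6106 and CG16957 (-4.95 ± 0.58, -4.22 without obe1/obe2 replicate 3, and -4.14 ± 0.58). The other shared rises were those of CG12560, Ir76a, CG14879, mey, CG13532, fd96Ca and CG3984, which was at 0.796 ± 1.38 in OreR, 85.3 ± 31.1 in obe1/obe2 and 246 ± 126 in obe2/Df (adjusted p = 0.00027 and 6.55e-05).

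Of 1445 genes called in both groups, 1392 changed in the same direction (687 higher, 705 lower) and 53 in opposite directions. After quantile normalization 745 shared genes were higher and 521 lower, so the larger side depends on the scaling. The shared lower genes numbered 447 and 455 without OreR replicates 1 and 3. The count of opposite directions moved most, to 608 without obe1/obe2 replicate 1. It was 10, 19 and 14 without OreR replicates 1, 2 and 3, 29 and 18 without obe1/obe2 replicates 2 and 3, and 32, 33 and 20 without obe2/Df replicates 1, 2 and 3. If calls were independent, 571.1 would have the same direction (284.3 higher, 286.8 lower). Because both comparisons use the same OreR libraries, 9 libraries without group differences were also simulated, with independent normal noise around the OreR means. The highest count over 100 simulations was 0. With no true change few genes pass in both comparisons by construction, so this 0 does not bear on shared controls where many genes differ. The correlation of the log2 fold changes across genes was 0.61, against a mean of 0.503 in the simulations, the covariance 0.812 against 0.0755, and the share of genes with the same sign 69.2% against 66.7%. Genes are not independent replicates, and 3 control libraries cannot be split into separate sets of at least 2 for each comparison, so part of the excess may come from the shared controls. In obe2/Df but not obe1/obe2, 3605 genes passed, of which 2475 also differed between the obe groups. In obe1/obe2 but not obe2/Df, 444 passed, of which 311 differed between them. Without OreR replicate 3 and obe1/obe2 replicate 3 in turn, 292 and 252 passed in obe1/obe2 alone, and without obe1/obe2 replicates 2 and 3 in turn, 198 and 162 of such genes differed between the groups. Of the 1392 shared genes 414 differed between the obe groups, and 218 without obe1/obe2 replicate 3 and 226, 264 and 210 without obe2/Df replicates 1, 2 and 3.

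**Figure D3:**
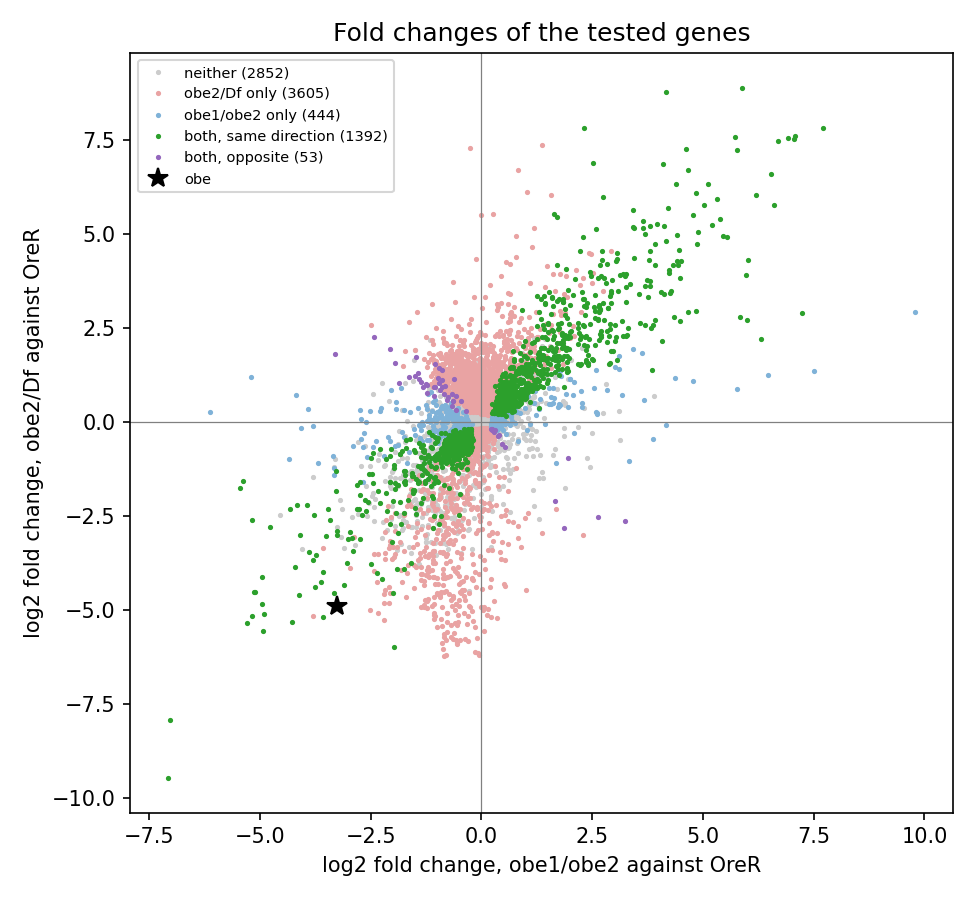
Log2 fold change against OreR of the 8346 tested genes in obe1/obe2 (x axis) and obe2/Df (y axis), with 1 point per gene, coloured by whether it passed in neither, either or both comparisons, and a star for obe. The 1392 genes called in both in the same direction lie in the lower left and upper right, and 3605 genes passed in obe2/Df alone.

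The direct comparison of obe2/Df with obe1/obe2 tested how the genotypes that share obe2 differ. Of 6 zygotic lists camera called 5 lower in obe2/Df. The early zygotic list had 0 higher and 15 lower of 20 (0 and 15 adjusted over the list alone), a median of -4.26 and a camera adjusted p = 0.000196. The gap list had 1 higher and 7 lower of 14 (1 and 9 adjusted over the list alone), with -3.48 and 0.0181. The cellularization list had 0 higher and 9 lower of 10 (0 and 10 adjusted over the list alone), with -2.52 and 0.00302. The pair-rule list had 0 higher and 7 lower of 16 (0 and 9 adjusted over the list alone), with -2.70 and 0.00464. The dorsal-ventral list had 0 higher and 8 lower of 26 (0 and 4 adjusted over the list alone), with -2.03 and 0.0381. Camera called none of these 5 with an estimated correlation (adjusted p = 0.791 for each), and fry passed the early zygotic and cellularization lists on direction (adjusted p = 0.0415 and 0.0243). The homeotic list had 0 higher and 2 lower of 11 (0 and 1 adjusted over the list alone) and did not pass camera (adjusted p = 0.338, and adjusted p = 0.812 with an estimated correlation). It passed without obe2/Df replicate 3 (adjusted p = 0.0331, with 4 lower). It had 1 lower without OreR replicate 1, obe2/Df replicate 2 or any 1 obe1/obe2 replicate. Without obe2/Df replicate 1, whose zygotic lists lay lowest, the medians of the 5 called lists were -2.75 (early zygotic), -1.87 (gap), -1.86 (cellularization), -1.35 (pair-rule) and -0.82 (dorsal-ventral). Without obe2/Df replicate 2 they were -5.32 (early zygotic), -4.40 (gap) and -3.51 (pair-rule), without obe2/Df replicate 3 -4.25 (gap) and -3.29 (pair-rule), and without obe1/obe2 replicate 2 -2.87 (gap). Without obe1/obe2 replicate 2, 5 cellularization, 3 pair-rule and 3 dorsal-ventral genes were lower, without obe1/obe2 replicate 3, 3 pair-rule and 5 dorsal-ventral genes, and without OreR replicate 3, 5 dorsal-ventral genes. The dorsal-ventral call was lost without obe1/obe2 replicate 2 (adjusted p = 0.0978), OreR replicate 1 (0.0537) or OreR replicate 2 (0.0642), and in a fit on the 6 libraries (0.0813). The gene slam was lower (log2 difference -1.77 ± 0.27, adjusted p = 0.00256), as were dpn (-3.29 ± 0.43), hh (-2.57 ± 0.60), kuk (-0.74 ± 0.17) and Kr (-3.04 ± 0.71, -2.15 without obe2/Df replicate 1).

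The spliceosome list had 1 higher and 14 lower of 29 (1 and 14 adjusted over the list alone), a median of -0.24 and a camera adjusted p = 0.00401. The adherens junction list had 1 higher and 8 lower of 13 (1 and 9 adjusted over the list alone), with -0.39 and 0.0381. The sex chromosome counting list had 1 higher and 8 lower of 19 (2 and 11 adjusted over the list alone), with -0.40 and 0.0278. The lower spliceosome members numbered 9, 6, 8 and 8 without obe1/obe2 replicate 2, obe1/obe2 replicate 3, obe2/Df replicate 1 and obe2/Df replicate 3. The adherens call was lost without obe1/obe2 replicate 1 (adjusted p = 0.0696) or 3 (0.0509) or obe2/Df replicate 3 (0.0607), and its lower members numbered 5 without obe1/obe2 replicate 2 or 3 and 3 without obe2/Df replicate 3. With an estimated correlation these 3 lists also had an adjusted p = 0.791. Lower genes included pea (-0.55 ± 0.06, adjusted p = 0.00118) and alpha-Cat (-0.46 ± 0.08, adjusted p = 0.00317). Of 14 pole cell genes 9 were higher and 1 lower in obe2/Df (9 and 1 adjusted over the list alone, median 0.74, camera adjusted p = 0.0639), with pgc (0.86 ± 0.17) and wun2 (0.96 ± 0.12) higher. The list passed without obe1/obe2 replicate 1 (adjusted p = 0.0221) and without obe2/Df replicate 2 (0.0378). With all libraries and an estimated correlation its adjusted p was 0.791. Higher genes also included Hsp26 (2.92 ± 0.37), Ku80 (1.71 ± 0.33) and Tep2 (2.04 ± 0.29), and lower ones Lsp1gamma (-1.80 ± 0.44). The largest rises were those of CG43050 from 2.73 ± 1.01 to 719 ± 266 (7.56 ± 0.86, adjusted p = 0.00124), Cyp6d2 (6.40 ± 0.68), mtsh (5.86 ± 0.67) and the near-identical copies Sdic3 (6.41 ± 0.48, 5.79 without obe1/obe2 replicate 1) and Sdic1 (5.999 ± 0.75). The largest falls were those of Dscam4 (-6.85 ± 1.28, -8.35 without obe2/Df replicate 2, -5.91 without obe2/Df replicate 3), CG13032 (-6.16 ± 1.06, -7.40 without obe2/Df replicate 2, -4.84 without obe2/Df replicate 3), amos (-6.08 ± 1.16, -4.75 without obe2/Df replicate 1, -7.66 without obe2/Df replicate 2) and CG18269 (-5.97 ± 1.02, -4.82 without obe2/Df replicate 1, -7.36 without obe2/Df replicate 2). Among them was also ato, at 425 ± 118 in obe1/obe2 and 24.5 ± 41.04 in obe2/Df (adjusted p = 0.00617).

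In this comparison 3730 genes (44.7%) passed, 2100 higher and 1630 lower in obe2/Df, and 4461 had an unadjusted p under 0.05. Of the 3730, 1427 differed at least 2-fold (1067 higher, 360 lower) and 227 at least 8-fold (63 higher, 164 lower). The lower genes numbered 997, 986 and 1005 without obe1/obe2 replicate 2, obe1/obe2 replicate 3 and obe2/Df replicate 3. Those lower at least 2-fold numbered 219 without obe1/obe2 replicate 2. Those lower at least 8-fold numbered 100 and 98 without obe1/obe2 replicate 2 and obe2/Df replicate 1, and those higher at least 8-fold 108 without obe1/obe2 replicate 1. After quantile normalization 1828 were higher and 2389 lower, 43.3% against 56.3% as deposited, which turned the larger side. TMM factors and edgeR left it, with 55.2% and 55.1% higher. Of the 28 lists camera called 8 (10 at an unadjusted p under 0.05) and 0 with an estimated correlation, and fry called 7 on direction and 23 on change either way.

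The mean of both obe groups against OreR asked what differs from OreR in the 6 obe libraries together. The early zygotic list had 1 higher and 9 lower of 20 (1 and 10 adjusted over the list alone), a median of -2.56 and a camera adjusted p = 0.0265. The ribosomal list had 0 higher and 10 lower of 28 (0 and 8 adjusted over the list alone), with -0.14 and 0.0121. The spliceosome list had 1 higher and 14 lower of 29 (1 and 14 adjusted over the list alone), with -0.20 and 0.0265. Each had an adjusted p = 0.957 with an estimated correlation. The early zygotic means per library, relative to OreR, were -0.89, 0.22 and -0.51 in obe1/obe2 and -6.54, -2.34 and -3.37 in obe2/Df. The fall in the mean of both groups therefore came mostly from obe2/Df. The spliceosome means were -0.21, -0.07 and -0.05 in obe1/obe2 and -0.34, -0.23 and -0.28 in obe2/Df. The RNA of obe was lower (log2 difference -4.08 ± 0.17, adjusted p = 1.9e-06). RpL3 was lower (log2 difference -0.81 ± 0.08, adjusted p = 0.000117), with Hen1 (-0.80 ± 0.07), Rho1 (-0.73 ± 0.07), Hsc70-4 (-0.60 ± 0.08), pea (-0.59 ± 0.05), U2af38 (-0.46 ± 0.08) and slam (-1.28 ± 0.24) also lower and CG11034 (7.09 ± 0.12) and CG7433 (6.57 ± 0.26) higher. In all 3550 genes (42.5%) passed, 1615 higher and 1935 lower, 1055 of them at least 2-fold (614 higher, 441 lower), and 4429 had an unadjusted p under 0.05. Without OreR replicate 1, 1242 were lower, 272 of them at least 2-fold. No list passed camera without OreR replicate 1 (adjusted p = 0.0732, 0.0868 and 0.0732), where 2 early zygotic and 9 spliceosome genes were lower. Without OreR replicate 2 the early zygotic list had an adjusted p of 0.0664. Of its genes 2 were lower without OreR replicate 2 or 3 or obe1/obe2 replicate 1 or 3, and 17 and 15 were lower without obe2/Df replicates 1 and 2 (median -1.77 without replicate 1).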

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

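The tests of the lower zygotic genes and the test of neighbours on 1 side of obe were chosen only after the result was seen, and among the former the scaling test replaced TMM factors, which left the early zygotic median at -4.82.

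Of 6 zygotic lists 5 were lower in obe2/Df than in OreR and than in obe1/obe2 by camera at its preset correlation, and 0 with an estimated one (adjusted p = 0.857 and 0.791 for each of the 5). Older embryos that had switched these genes off would keep later genes level. The pair-rule and segment polarity median was instead -3.55 (95% bootstrap interval -4.20 to -2.43). A factor per library would move maternal and early zygotic lists alike, but their medians differed by -4.99 (-5.51 to -4.05). Both intervals resample list genes, so they do not measure the spread between libraries. In the obe2/Df libraries the pair-rule medians were -6.81, -2.08 and -2.14, and the early zygotic medians -7.77, -2.63 and -3.41. The early zygotic values argue against scaling in each library, as the cleared maternal RNA medians were 0.27, 0.17 and 0.15. The pair-rule values go against older embryos, but that list is 1 of the 5 that make up the pattern. It also shares run with the early zygotic list. The homeotic list, also of later genes, had a median of -0.52 in obe2/Df replicate 3, so older embryos are not excluded there. A smaller share of embryos with zygotic transcription (younger, unfertilized or arrested) stays open, since 5 list medians lay at -1.51 or lower in each obe2/Df library and the cleared maternal RNA medians at 0.27, 0.17 and 0.15, but the homeotic median was -4.21, -1.59 and -0.52, near OreR in replicate 3. Loss of obe stays open too, as the early zygotic mean ranged over 4.19 (log2) among the obe2/Df libraries and the obe1/obe2 median was -0.28 with no list call. The design has 1 group with the deficiency, so loss of obe, the deficiency and embryo collection cannot be told apart.

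Changes of at least 8-fold in the same direction in both obe groups involved 103 genes, 75 higher and 28 lower. Of these, 58 (56.3%) lie on chromosome 3, where obe lies, against 43.7% of 8194 matched tested genes (odds ratio 1.67, 95% interval 1.11 to 2.53, Fisher's exact test, two-sided, p = 0.0121). Sequence or expression variants carried on the obe-bearing chromosome, a stock background, could therefore contribute. The 58 include obe itself (-3.26 in obe1/obe2 and -4.91 in obe2/Df), and the test treats neighbouring genes as independent. The median level on the higher side was 85.3 normalized counts (95% bootstrap interval 52.7 to 141, against a bound of 50). This argues against most of these genes having fewer than 50 counts on that side. It does not exclude low read depth for genes below the median or on the lower side. The genes had also passed the filter and both tests, which favour higher counts. No group carries the same background without obe alleles, so an effect of obe on these genes remains untested.

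Genes on 1 side of obe were lower in obe2/Df than in obe1/obe2. Of the 20 tested neighbours on that side 15 were lower and 0 higher, with a median of -0.83 (56.3% of the level), against 19.5% of all tested genes being lower, and examples chosen after their values were seen are ea (-1.44, adjusted p = 0.000188), Sra-1 (-1.42, adjusted p = 0.000103) and FK506-bp1 (-1.20, adjusted p = 0.000502). A deficiency that removes most of the 21 genes centred on obe is argued against, as 53.7% of 8052 windows elsewhere had a median as low. That median would miss a deficiency of only a few genes. The nearest tested gene on each side was lower in obe2/Df than in obe1/obe2, Atx2 (-0.77, adjusted p = 0.0121) and CG18522 (-0.68, adjusted p = 0.0258). A deficiency that extends to 1 side may account for the lower neighbours there. The test of this was chosen after that side was seen to be lower, so it is not separate support. In it 0.211% of windows had a median as low as the window ending at obe. The window on the other side had a median of 0.26 and a percentile of 89.4. The neighbours were at -0.99 in obe2/Df and -0.13 in obe1/obe2 against OreR, and the labels do not give the deficiency's extent.

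Other results that differ between the obe groups by a direct test are 3730 genes, obe at -1.65 and crb at 0.57. They also include 53 of the genes called in both obe comparisons with opposite directions. That count was 608 without obe1/obe2 replicate 1, and 10 to 33 without each of the other libraries. Of the 42 genes named for the largest changes, 26 also differ. The 42 include the genes named for the largest called changes between the obe groups, which pass this test by selection. The share of 26 in 42 therefore does not measure how often genes with large changes differ between the groups. The list medians that differ by camera at its preset correlation, and in 0 of 8 lists with an estimated one (adjusted p = 0.791 for each), are -4.26 (early zygotic), -3.48 (gap and terminal), -2.70 (pair-rule), -2.52 (cellularization), -2.03 (dorsal-ventral), -0.40 (sex chromosome counting), -0.39 (adherens junction) and -0.24 (spliceosome).

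The libraries were also regrouped in other ways. These fits hold only 2 groups at a time, so their counts differ from the 1889, 5050, 3730 and 3550 of the fit with 3 groups. For each pair of groups there are 10 splits, too few for a share under 0.05. In each pair 1 of the 10, the real one, gave as many genes, with 1351, 5181 and 3350 genes in obe1/obe2 against OreR, obe2/Df against OreR and obe2/Df against obe1/obe2, and the highest other split gave 0 by limma. For OreR against the 6 obe libraries, a fit that pools the obe groups into 1 gave 1760 genes (3550 with 3 groups). Of 84 splits 2, the real one among them, gave as many, a share under 0.05. The other, with 3741 genes, set the obe2/Df libraries against the rest, which points to the structure of the samples. For genes called in the same direction in both comparisons 2 of 100 drawn splits, the real one among them, gave at least the real 1392. The highest other, 2139, took obe2/Df as the shared group, which again follows the genotypes. Because the splits mix libraries of 3 genotypes, they are not a null without differences, and they do not exclude chance.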

How the results depend on the processing

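The fits on 6 libraries, the shared count from the authors' deposited tables and the gene families were chosen only after the data were seen. Each count of genes stayed within 1.5 times its reported value under other pseudocounts, filters, TMM factors, quantile normalization, edgeR, DESeq2 and the 6-library fits (1351, 5181 and 3350 for the pairs of groups, and 1069 shared). Array weights raised obe1/obe2 to 3451 genes, and the cause was not tested. A minimum fold of 2 left 694 (obe1/obe2), 1895 (obe2/Df), 1427 (obe2/Df against obe1/obe2), 1055 (mean) and 478 (shared), by construction. The authors' deposited tables call 525 in obe1/obe2, 1559 in obe2/Df and 386 in both, and the cause was not tested. With an estimated correlation camera called 0 lists in each comparison, down from 8, 8 and 3 in obe2/Df, obe2/Df against obe1/obe2 and the mean, where the estimated correlation between members replaces the preset 0.01. With the replicate number as a block the counts were 1581, 4854, 3370 and 3299, and 1154 shared. Correlations between libraries of the same number were -0.04, -0.14, -0.01, -0.01, 0.08, -0.20, 0.52, 0.38 and 0.01. Not each library correlated best with its own number, so the numbers do not pair all libraries. However, obe1/obe2 replicate 1 was at 0.52 with obe2/Df replicate 1 and at -0.44 and -0.37 with replicates 2 and 3. Pairing of some obe libraries is therefore not excluded.

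Leaving out 1 library gave 1301 to 2211 genes in obe1/obe2, 4194 to 5188 in obe2/Df, 2583 to 4034 between the obe groups, 2377 to 4124 for the mean and 970 to 1523 shared. Lists called by camera then ranged from 0 to 1, 6 to 9, 7 to 10 and 0 to 7. Of 3723 alternatives for 318 named values, 3498 kept direction and call, 165 lost the call, 54 gained it and 6 reversed. Of 2862 leave-one-out values, 2672 kept both, 159 lost the call, 28 gained it and 3 reversed. The reversals were in immunity genes that did not pass in obe1/obe2. PGRP-SB1 (0.21) was at -0.22 with array weights, and -0.14 to 0.43 over left-out libraries. PGRP-SC2 (-0.02) was at 0.042 with a pseudocount of 5, 0.55 with array weights, 0.23 with edgeR, 0.22 with DESeq2 and 0.22 in the authors' deposited table, and -0.63 to 0.83 over left-out libraries. The cause was not tested. A change of 1.5-fold was found in 43.3% and 29.9% of the genes changed by that fold in the simulated obe1/obe2 and obe2/Df comparisons. These came from separate draws of genes with the same spread in all groups, so their difference does not measure sensitivity.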

Other observations

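The gene families were chosen after their values were seen. Proteasome subunit genes, whose products degrade ubiquitinated proteins, had more lower than higher called members in both obe groups. Of 30 tested subunits 26 were lower and 1 higher in obe1/obe2 (median -0.51, camera adjusted p = 5.08e-08, and adjusted p = 0.24 with an estimated correlation), with 19 to 27 lower when 1 library was left out. In obe2/Df 17 were lower and 4 higher (median -0.39, camera adjusted p = 0.00984, and adjusted p = 0.61 with an estimated correlation). Prosbeta5 was at -0.65 ± 0.08, adjusted p = 0.000588 in obe1/obe2 and -0.71 ± 0.08, adjusted p = 0.000241 in obe2/Df, and Rpt1 at -0.31 ± 0.07, adjusted p = 0.0157 and -0.29 ± 0.07, adjusted p = 0.00896. Rpn2 was lower in obe1/obe2 (-0.62 ± 0.15, adjusted p = 0.0157) and did not pass in obe2/Df (-0.11 ± 0.15, adjusted p = 0.528). In the direct comparison 11 subunits were higher in obe2/Df and 0 lower, with 2, 1 and 4 lower without OreR replicate 1, OreR replicate 2 and obe1/obe2 replicate 1. With TMM factors 26 and 17 subunits were lower in the obe groups, and 11 were higher and 1 lower in the direct comparison.

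Of 9 small nuclear RNA genes 5 were lower and 1 higher in obe1/obe2 (median -2.14, camera adjusted p = 0.00999, and adjusted p = 0.336 with an estimated correlation). In obe2/Df 6 were lower and 1 higher (median -2.33, camera adjusted p = 0.0297, and adjusted p = 0.61 with an estimated correlation), and 5 to 6 were lower when 1 library was left out. The higher 1 was lost in obe1/obe2 without OreR replicate 1 or 3 or obe1/obe2 replicate 1 or 2, and in obe2/Df without OreR replicate 1 or 3 or any 1 obe2/Df replicate. Several are near-identical copies, so their reads are of uncertain origin. How well TruSeq v2 libraries capture small nuclear and small nucleolar RNAs was not tested, so these counts need not follow their levels in the embryos. Of 17 small nucleolar RNA genes 4 were lower in obe1/obe2 and 6 in obe2/Df (medians -0.46 and -0.35, camera adjusted p = 0.0984 and 0.153). In obe1/obe2 this was 1 without OreR replicate 1 or 2 or obe1/obe2 replicate 1 or 3, and 2 without obe2/Df replicate 2. In obe2/Df 3 were lower and 1 higher without OreR replicate 1. Mitochondrial ribosomal protein genes (72 tested) had 5 higher and 7 lower in obe1/obe2 and 23 and 17 in obe2/Df. In obe1/obe2, 4 were lower without OreR replicate 1 or 3 and 13 without obe1/obe2 replicate 1, and 3 were higher without OreR replicate 3 or obe1/obe2 replicate 3. In obe2/Df 11 were lower without obe2/Df replicate 1. Cytochrome P450 genes (36) had 8 and 8, then 11 and 11. In obe1/obe2, 4 were higher without OreR replicate 1 and 5 without OreR replicate 3 or obe1/obe2 replicate 3, and in obe2/Df 7 were lower without OreR replicate 2. Glutathione transferase genes (33) had 7 and 11, then 8 and 12, with 5 higher in obe2/Df without obe2/Df replicate 3.

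The posterior determinant gene osk, chosen after its values were seen, was at 28266 ± 1064 in OreR, 16462 ± 10069.6 in obe1/obe2 and 66879.7 ± 10263 in obe2/Df. It was higher in obe2/Df than in obe1/obe2 (2.18 ± 0.34, adjusted p = 0.00259).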
